A study of Gallus gallus with 34 samples.

How the data were processed

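Long and small RNA were sequenced from chicken liver and sperm in 34 samples, 17 of each kind of RNA. Per the labels, Arbor Acres breeder roosters were fed a basal diet with added folate at 0 (CON), 0.25 (FS1), 1.25 (FS2), 2.50 (FS3) or 5.00 (FS4) mg per kg from 1 day of age. Liver was taken from single CON and FS2 roosters at 35 weeks, with 3 birds per group. Liver of 1-day-old broiler offspring of CON and FS2 fathers was pooled from 4 chicks per library, all from the same replicate and so from 1 father, with 3 pools per group. The hens that produced the chicks all received a diet with extra folate. Sperm RNA was pooled from 5 roosters at each of the 5 levels, 1 library per level, so sperm has no replicates. The long-RNA libraries were made with rRNA depletion and a strand-specific kit, per the labels' protocols.

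The submitters' processing notes name FastQC, Bowtie2 2.0.6, TopHat, Cufflinks, Cuffdiff and DESeq, and the chicken build galGal4, without saying which step each served. The 6 deposited expression tables hold mRNA genes, lncRNA transcripts and miRNAs for liver and for sperm. The long-RNA values are FPKM, fragments scaled by transcript length and library size, computed by the authors, per the file headers. FPKM carry no read totals, so the depth behind the long-RNA values is unknown and no counting interval is given. The miRNA tables hold raw values that the authors deposited, which are expected counts, and a signal that is the authors' normalized value. Of all raw values, those of 0 included, 12.1% in liver and 12.33% in sperm are not whole numbers. Within a library the authors' normalized value is the raw value times 1 factor, between 0.6354 and 1.9622 in liver and between 0.8199 and 1.2421 in sperm. Total miRNA counts over unique sequences were 1666169 to 7297278 per liver library (lowest in broiler FS2 3, highest in rooster CON 3) and 315267 to 498970 per sperm library (lowest in FS2, highest in FS1). A further 18 deposited tables list the authors' own comparisons, with FPKM or normalized values, log2 fold changes and unadjusted p-values, per the file headers. They were used only to describe what they list. A further 32 columns of per-sample values, copies of the sperm values within those tables, were not used. Genes are named as the deposited tables name them, and coordinates are those of the tables. No genome sequence was used here.

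The liver mRNA table has 29245 rows, of which 15948 carry a gene symbol or Ensembl identifier and entered the tests. The other 13297 rows entered only as an alternative. The sperm mRNA table has 26252 such rows among 224258. Each lncRNA transcript was 1 row (9127 in liver, 122378 in sperm). Identical miRNA sequences listed more than once were counted once, leaving 1991 of 2252 liver rows and 1906 of 2177 sperm rows. Lines without values (1 each in the liver mRNA and lncRNA tables, 30 in the liver miRNA table and 24 in the sperm miRNA table) were not used here.

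Liver mRNAs and lncRNAs were tested with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend) on log2(FPKM + 1). Rows entered with a mean of at least 1 FPKM for mRNAs or 0.5 for lncRNAs over the libraries of the fit, and a call was a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are on this scale, which understates changes of low rows. FS2 was compared with CON separately in rooster and in broiler liver, because single birds and pools can differ in spread. The difference between the 2 folate effects was tested as an interaction over all 12 libraries, and rooster liver was compared with broiler liver as the mean of both diet groups at each stage. Liver miRNAs were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) on the expected counts rounded to whole numbers, with DESeq2 1.42.0 as an alternative. Fold changes of rooster and broiler liver were correlated across genes, with a permutation test that regrouped the diets within each stage. Sperm levels were set against CON as log2 ratios of value + 1 and described by a 2-fold size rule, with no test. Means had to reach 1 FPKM for mRNAs, 0.5 for lncRNAs and 10 for normalized miRNA values.

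A set of 27 gene lists covered folate and methyl metabolism, energy and lipid metabolism, proliferation, translation, stress, immunity and the cell types of liver, blood and reproductive tract. Of their members, 512 of 646 were matched in the liver table and 523 of 657 in the sperm table. Lists with at least 5 tested members, 26 of them, were compared with all other genes by camera in limma, with a preset correlation between genes of 0.01 and, as an alternative, the correlation estimated from the data. In sperm, each list's median was placed among 10000 random lists of the same size matched on expression. Another 5 lists of genes of other organs (heart muscle, fast skeletal muscle, smooth muscle, stomach and intestine) were written after cardiac and gastric genes had been seen in single broiler pools.

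The samples and groups, the tests, the gene lists, most alternatives and the rule for the genes named in the text were fixed before the data were examined. By that rule, with only genes that have a symbol, the 10 largest rises and 10 largest falls past the threshold are named. Where under 5 pass in a direction, the genes of smallest unadjusted p up to 5 are named. Up to 4 past the threshold, or the 2 of smallest p, are named for each gene list that passes and for the lists of folate, methionine, glucose, fatty acid and cholesterol metabolism. In the stage comparison up to 2 members are named per list. In sperm the 10 highest and 10 lowest genes, or 5 miRNAs, that passed 2-fold in the same direction at all 4 levels qualify. LncRNAs are limited to 2 per direction, and from the authors' tables the genes listed at both stages are named. Names outside the rule are said to be so, and 1 gene that the rule names is not reported here.

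Alternatives were another pseudocount, other minimum values, no minimum, median centring, robust moderation, the replicate number as a block, all liver libraries in 1 fit, DESeq2 and its size factors, and leaving out each library in turn. Added after the data had been seen were all rows, values of 0 taken as missing, small-RNA rows removed, miRNA sequences summed by name, CON libraries only in the stage comparison, the list tests by stage and of the difference, and leaving out broiler CON pools 1 and 2 together. The last leaves 1 CON pool, which is then assumed to vary like the other libraries.

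The liver tests and the sperm size rule were tested on simulated data with known changes. Of 100 genes changed by log2 1 and 100 changed by log2 2, limma found 25 and 74 in the rooster design, 73 and 90 in the broiler design, 27 and 81 for the interaction and 82 and 99 by stage. The same shifts gave 20 and 62 for rooster lncRNAs and 57 and 94 for broiler lncRNAs. Of 30 miRNAs per size, edgeR found 4 and 23 in the rooster design, 9 and 27 in the broiler design and 21 and 28 by stage. Unchanged mRNA genes called were 5 in the rooster design, 7 in the broiler design, 7 for the interaction and 6 by stage. Noise was drawn for each row on its own, while real genes of a library can vary together. Both sizes were changed in the same run, which eases the adjusted threshold. The real tests may therefore find smaller shares. The sperm size rule found 0 of 100 genes at 1.5-fold and 100 of 100 at 3-fold. The simulated noise was smaller than the spread of the real log2 ratios (SD 0.34 to 0.43 for mRNAs and 0.71 to 0.94 for miRNAs). That outcome therefore followed from the rule itself and gives no error rate for the sperm libraries. Correlations of mRNA values within liver groups were 0.919 to 0.977, which without depth cannot be set against sampling noise. For miRNA counts within liver groups no pair was alike within sampling noise, and the lowest chi-square per degree of freedom was 60.25. Work outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.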

Results

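Liver and sperm RNA of Arbor Acres chickens, a broiler breed, were profiled to ask whether the folate that breeder roosters eat is reflected in their own liver, in their sperm and in the liver of their chicks. Folate is a vitamin that carries one-carbon units for nucleotide synthesis and for methylation. Liver was compared between CON (no added folate) and FS2 (1.25 mg per kg), with 3 single roosters aged 35 weeks per group and 3 pools of 4 one-day-old chicks per group of fathers. Rooster sperm was profiled as 1 pool of 5 birds at each of 5 folate levels, so no sperm value has a replicate. The depth behind the FPKM values is unknown, and FPKM per liver library summed to between 756134 (rooster FS2 1) and 1614118 (broiler CON 3). Liver miRNA libraries held 1666169 to 7297278 counts and sperm libraries 315267 to 498970. Values below are mean ± SD with n = 3 libraries per diet group or n = 6 per stage unless stated.

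In the liver of the roosters themselves, no single gene passed the test by diet, and the genes named here are those of smallest p in each direction. BG1, a butyrophilin-like B-G protein of the chicken major histocompatibility region (chromosome 16, 114087 to 119468), was at 26.5 ± 4.77 FPKM in FS2 and 7.10 ± 2.18 in CON, a 3.73-fold ratio (log2 1.78, SE 0.25, limma adjusted p = 1.00). CARD10, a scaffold protein of NF-kappaB signalling, was at 3.85 ± 0.876 against 1.37 ± 0.507, and GATA5, a transcription factor of endoderm and heart, at 12.2 ± 2.74 against 5.90 ± 0.823. ABCA12, a lipid transporter, was at 30.6 ± 5.62 against 10.2 ± 6.03, and SMARCAD1, a chromatin remodelling enzyme, at 2.19 ± 1.06 against 0.258 ± 0.0290. On the lower side stood B3GLCT, a glucosyltransferase of secreted proteins (3.75 ± 0.336 in FS2 against 6.40 ± 0.655), U3, a small nucleolar RNA of rRNA processing (8207 ± 2175 against 24990 ± 11355), MUSTN1 (1.41 ± 0.746 against 6.41 ± 4.48), COL17A1, a hemidesmosome collagen (0.357 ± 0.452 against 2.71 ± 1.94), and ZYX, a focal adhesion protein (13.4 ± 1.75 against 22.4 ± 3.70). Of 9716 genes tested, limma called 0, with 139 at an unadjusted p under 0.05 where chance gives 486. Leaving out 1 rooster gave 1 lower call without CON 2, 2 lower without CON 3, 1 higher without FS2 1 and 1 higher without FS2 3.

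As groups, 3 of 26 gene lists fell in FS2 rooster liver by camera with its preset correlation. The stellate cell and fibroblast list, the matrix-making cells of liver, fell with 14 of 16 members below 0 (median log2 -0.32, adjusted p = 0.00156). LUM, a matrix proteoglycan, was at 12.2 ± 0.885 against 17.0 ± 1.95, and COL5A1 at 6.28 ± 1.97 against 8.70 ± 1.27. The cholesterol synthesis list fell with 18 of 20 members below 0 (median -0.25, adjusted p = 0.0162), among them the sterol enzymes NSDHL (3.43 ± 1.45 against 5.02 ± 0.936) and LSS (9.00 ± 3.40 against 13.6 ± 3.50). The cytosolic ribosomal protein list fell with 54 of 58 members below 0 (median -0.17, adjusted p = 0.0281), with RPS16 at 773 ± 231 against 997 ± 180 and RPL38 at 558 ± 166 against 758 ± 293. Each of the 3 had an adjusted p = 0.912 with an estimated correlation, and 0 members of each passed when adjusted over the list alone. The ribosomal list had an adjusted p of 0.762 without CON 2 and 0.170 without CON 3, and turned to higher in FS2 without FS2 1 (0.0142). The cholesterol list was at 0.730 without CON 3, 0.648 without FS2 1 and 0.123 without FS2 3, and the stellate list at 0.538 without FS2 3. The number of lists past the test was 6 without CON 1, 8 without FS2 1 (7 of them higher) and 7 without FS2 2.

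The enzymes that handle folate itself did not pass as a list in roosters. In folate and one-carbon metabolism, GLDC, of the glycine cleavage system, was at 78.2 ± 20.8 in FS2 against 56.4 ± 18.5 in CON, and MTR, methionine synthase, at 12.5 ± 0.818 against 14.7 ± 1.98. In the methionine cycle, the phosphatidylcholine-forming methyltransferase PEMT was at 132 ± 2.34 against 92.8 ± 15.1 and SARDH, sarcosine dehydrogenase, at 19.6 ± 10.5 against 32.9 ± 11.5. In glycolysis, LDHB was at 533 ± 123 against 301 ± 84.2 and PFKL at 24.2 ± 4.70 against 19.1 ± 1.25. In fatty acid synthesis, the desaturase FADS2 was at 27.9 ± 5.47 against 44.9 ± 23.0 and the lipogenic regulator row THRSP,THRSPB at 463 ± 621 against 422 ± 84.7. In fatty acid oxidation, EHHADH was at 247 ± 33.6 against 167 ± 27.4. In each of these lists 0 members passed, over all genes or when adjusted over the list alone.

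In the liver of 1-day-old chicks, 1 row passed the test by the diet of the father. It is named uc_338, an ultraconserved-element RNA family that the table places on chromosome 6 (7269404 to 7420110). It was listed at 0 in all 3 CON pools and at 26.6, 35.6 and 29.7 FPKM in the FS2 pools (log2 4.97, SE 0.13, limma adjusted p = 2.23e-06). In roosters it was listed at 0 in all 3 CON birds and at 30.1, 0 and 129.5 in FS2, and the call was lost (adjusted p = 1.00) with all 12 liver libraries in 1 fit. A value of 0 can be a failed estimate: of 79 liver rows named uc_338, 20 were at 0 in at least 1 library and at 10 or more in another. Next by p, and not past the threshold, were OSBPL10, an oxysterol-binding protein (14.7 ± 1.98 in FS2 against 9.08 ± 0.963 in CON), NRARP, a Notch pathway regulator (15.4 ± 3.00 against 6.94 ± 2.36), BMAL1, a core transcription factor of the circadian clock (3.96 ± 0.197 against 2.53 ± 0.200), and CDKN3, a cell cycle phosphatase (6.46 ± 0.460 against 4.25 ± 0.611). BMAL1 was the only member of the circadian clock list to pass when adjusted over the list alone. On the lower side were GSTA3, a glutathione transferase (7.25 ± 0.826 against 12.9 ± 0.981, log2 -0.75, limma adjusted p = 0.867), LGALS1, galectin-1 (5.34 ± 0.511 against 7.98 ± 0.615), MYL9, a smooth muscle myosin light chain (4.89 ± 0.540 against 7.11 ± 0.282), the signal recognition particle RNA row Metazoa_SRP (21.5 ± 10.9 against 66.8 ± 26.5) and CDC6, a replication licensing factor (2.64 ± 0.331 against 4.20 ± 0.473). Of 9640 genes tested, limma called 1, with 272 at an unadjusted p under 0.05 where chance gives 482. The count was 3 (2 lower) without CON 1, 2 (1 lower) without each of CON 3 and FS2 3, and 7 (4 lower) without CON 1 and CON 2 together, a choice made after the data had been seen.

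**Figure D1:**
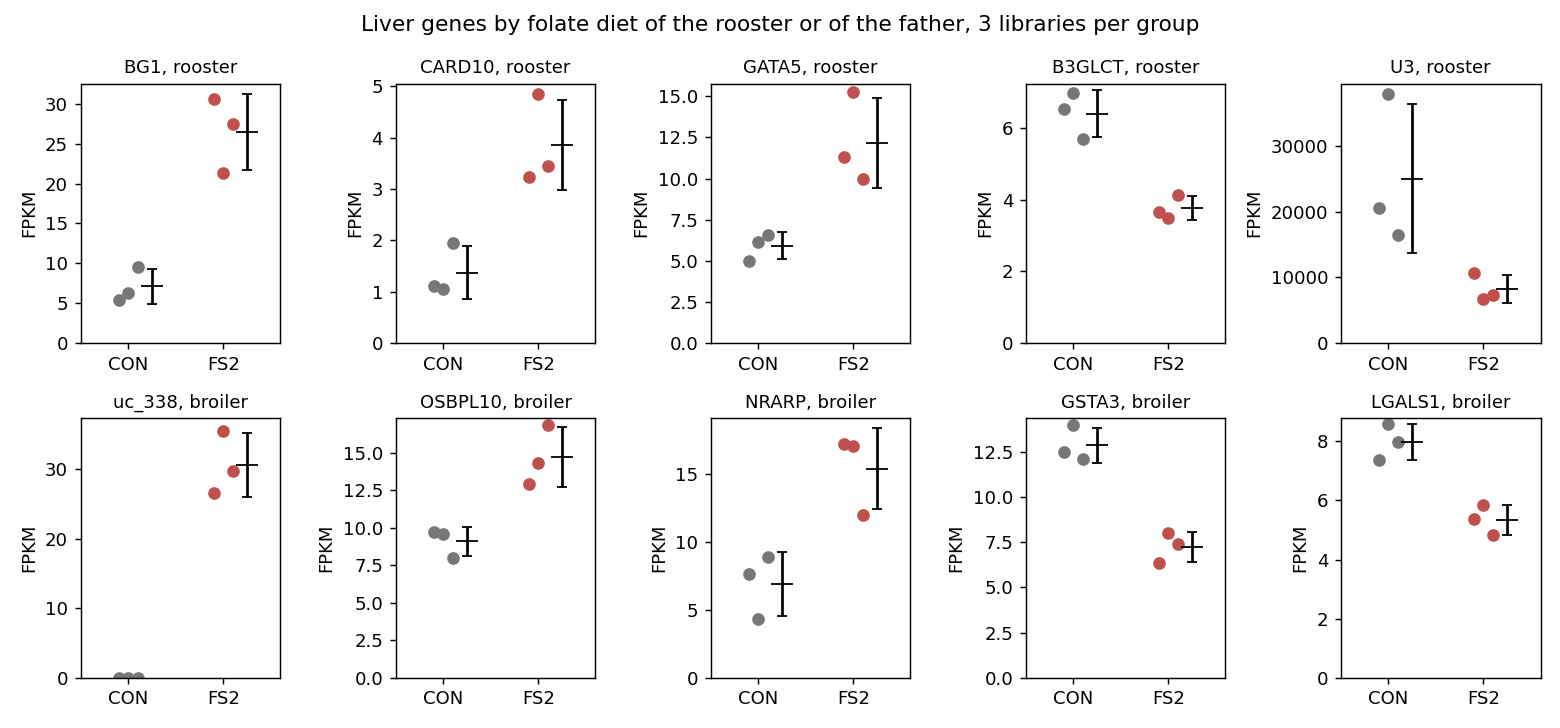
FPKM of 5 genes in rooster liver (top) and 5 in broiler liver (bottom) by diet of the rooster or father, with a point per library and a bar for the mean ± SD of 3 libraries per group. BG1 sits at 26.5 ± 4.77 FPKM in FS2 and 7.10 ± 2.18 in CON, uc_338 is listed at 0 in each broiler CON pool (no bar drawn), and uc_338 alone passed the adjusted test.

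Of 26 gene lists, 6 fell in FS2 broiler liver by camera with its preset correlation. Cytosolic ribosomal proteins fell with 56 of 58 members below 0 (median log2 -0.21, adjusted p = 1.58e-06; adjusted p = 0.831 with an estimated correlation), with RPL36 at 744 ± 195 against 1265 ± 52.0 and RPS21 at 102 ± 27.1 against 141 ± 48.7. Oxidative phosphorylation, the mitochondrial respiratory chain, fell with 29 of 33 members below 0 (median -0.19, adjusted p = 0.000261; 0.831 as the adjusted p with an estimated correlation). Its members of smallest p lay on rows shared with another gene, ATXN3,NDUFB1 (39.4 ± 7.76 against 29.7 ± 3.67) and IQUB,NDUFA5 (68.9 ± 17.5 against 96.7 ± 28.4). Stellate cells and fibroblasts fell with 16 of 17 members below 0 (adjusted p = 1.75e-06), among them the contractile proteins TAGLN (6.33 ± 0.913 against 11.6 ± 3.47) and DES (12.2 ± 3.20 against 25.1 ± 14.8). Endothelial cells fell with 15 of 17 members below 0 (adjusted p = 0.0013), with FLT1, a VEGF receptor, at 2.46 ± 0.342 against 3.12 ± 0.223 and ERG at 2.75 ± 0.634 against 3.43 ± 0.117. Glycolysis passed as lower with 10 of 16 members below 0 and 6 above (median -0.020, adjusted p = 0.0296), with LDHA at 81.3 ± 11.4 against 124 ± 18.6 and ALDOC at 12.7 ± 1.99 against 18.6 ± 2.86. Heterophils, the avian counterpart of neutrophils, fell with 6 of 7 members below 0 (adjusted p = 0.0296), with the lysozyme LYG2 at 5.86 ± 2.13 against 11.1 ± 4.42 and the cathelicidin CATHL1 at 1.20 ± 0.911 against 2.29 ± 0.763. For these last 4 lists the adjusted p = 0.707 with an estimated correlation, and 0 members of any of the 6 passed when adjusted over the list alone.

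These list calls rested on single pools and settings to different degrees. Without CON 3 the ribosomal list turned to higher in FS2 (adjusted p = 0.950), and without FS2 2 it was at 0.0787. Oxidative phosphorylation was at 0.950 without CON 3 and 0.224 without FS2 2, and endothelial cells at 0.238 without FS2 3. Glycolysis was at 0.122 without CON 1, 0.4998 without CON 3, 0.0787 without FS2 2, 0.0588 without FS2 3 and 0.112 without a minimum value, and heterophils at 0.207, 0.120 and 0.146 without CON 1, CON 3 and FS2 2. The number of lists past the test was 11 (9 lower) without CON 2, and 3 without each of CON 3 and FS2 2. In the stellate list, DES was at 42.1 FPKM in CON 2 against 18.7 and 14.7 in CON 1 and CON 3, and TAGLN at 14.3 and 12.9 in CON 1 and CON 2, the pools that carried transcripts of other organs, against 7.67 in CON 3 and 5.36 to 7.18 in FS2. Without CON 1 and CON 2 together, stellate cells were at 0.119, endothelial cells at 0.0625 and heterophils at 0.354.

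The lists of folate, methyl, fatty acid and cholesterol metabolism did not pass in broiler liver, with 0 members past the threshold over all genes or when adjusted over the list alone. TYMS, thymidylate synthase, was at 10.6 ± 1.92 in FS2 against 13.2 ± 2.42 in CON, and FPGS, which adds glutamates to folate, at 60.5 ± 7.63 against 49.8 ± 6.97. SARDH was at 26.6 ± 3.64 against 21.9 ± 2.07 and PEMT at 147 ± 11.6 against 123 ± 22.6. In fatty acid synthesis, ATP citrate lyase (acl) was at 119 ± 23.9 against 93.4 ± 21.8 and the lipogenic transcription factor SREBP-1 at 31.5 ± 11.3 against 22.9 ± 9.42. In cholesterol synthesis, INSIG1, an endoplasmic reticulum protein that restrains sterol synthesis, was at 55.0 ± 13.9 against 34.7 ± 10.4 (unadjusted p = 0.0328) and the FDPS row at 18.2 ± 2.47 against 14.2 ± 1.63. In fatty acid oxidation, PPAR was at 40.5 ± 2.28 against 45.3 ± 3.25 and ACSL1 at 266 ± 34.7 against 238 ± 31.7.

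Beside these comparisons, 2 of the 3 broiler CON pools carried transcripts of other organs. In CON 2 the heart muscle list had a median of 9.95 FPKM against 0.0595 in the other 5 pools. Of its 21 matched genes, 18 were over 5 times the median of those pools, 16 of them at 1 FPKM or more. NPPB, a cardiac natriuretic peptide, was at 513.7 FPKM in that pool, the ventricular light chains MYL3 and MYL2 at 94.6 and 54.7, cardiac actin ACTC1 at 51.4 and cardiac troponin TNNT2 at 14.0. FS2 1 stood next to it at a far lower level, with a heart list median of 0.138 FPKM, 2.32 times the others, and 5 genes over 5 times them, 0 of these at 1 FPKM or more. Summed over its sequences, miR-499, a heart and slow muscle miRNA chosen after its values were seen, was at 17300 (authors' normalized value) in CON 2, 776.5 in FS2 1, 542 in CON 1 and 110 to 172 in the other 3 pools. In CON 1 the stomach list had a median of 2.34 FPKM against 0.0210 in the others, and 12 of 19 matched genes were at 1 FPKM or more and over 5 times the others. The gastric mucosal proteins GKN2 and CLDN18 were at 908.5 and 14.8 FPKM there, the gastric protease CTSE at 34.4 and VSIG1 at 24.2. Of the other stomach genes that passed, CHIA and GIF were also high in every rooster liver (314 to 950 and 56.1 to 156 FPKM). PGA, pepsinogen, and ATP4B, a subunit of the gastric proton pump, which brought the stomach list up and are not on it, were at 284 and 49.5 in CON 1 and at no more than 0.0688 in any other broiler pool.

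**Figure D2:**
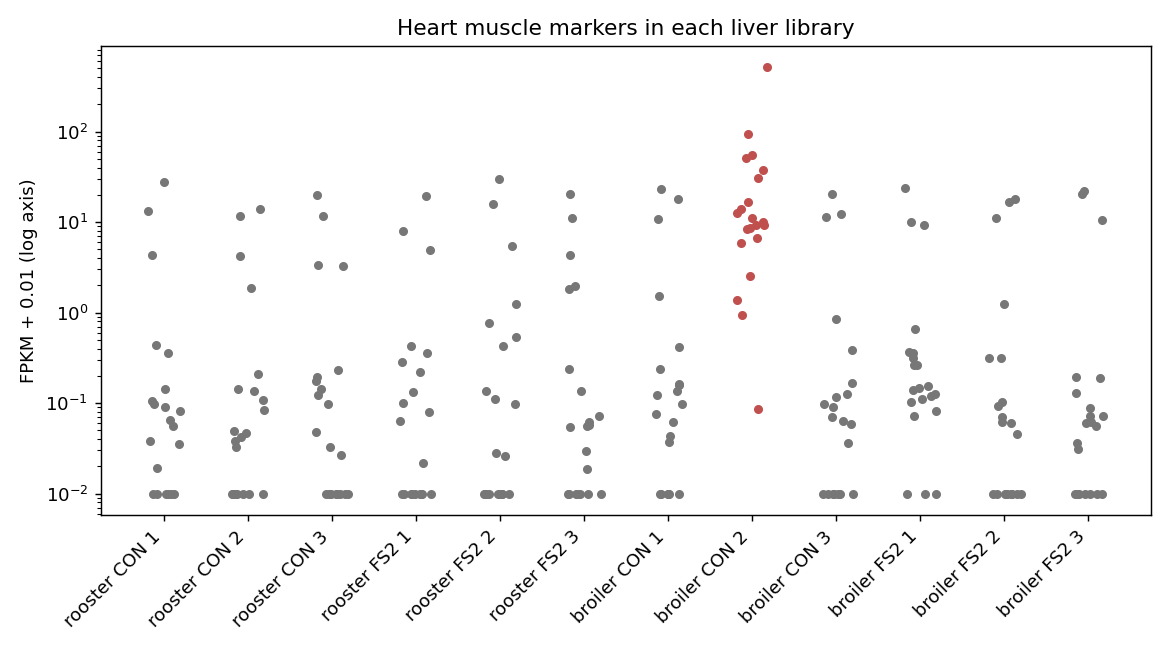
FPKM + 0.01 (log axis) of 21 heart muscle genes in each of the 12 liver libraries, with a point per gene and broiler CON 2 in red. The median in that pool is 9.95 FPKM, against 0.0595 over the other 5 broiler pools.

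Whether the diet acted alike in fathers and chicks was tested as a difference between their folate effects. SMARCAD1 and OSBPL10 had the smallest p in each direction. The difference was 1.89 on the log2 scale for SMARCAD1 (SE 0.37, unadjusted p = 0.000258) and -1.46 for OSBPL10 (unadjusted p = 0.000337), which was at 8.11 ± 2.36 FPKM in FS2 and 14.9 ± 2.96 in CON roosters. BG1 (2.16), BFIV21, an MHC class I gene (2.40), ST6GALNAC2, a sialyltransferase (1.36), and ADAMTS19 (0.90) were more in favour of FS2 in roosters. TNIK (-0.81), B3GLCT (-0.71), MYO1G (-1.44) and ZYX (-0.73) were more so in chicks. Of 9869 genes, limma called 0, with 130 at an unadjusted p under 0.05 where chance gives 493. The count was 1 without rooster CON 2, 1 without rooster FS2 1, 3 without rooster FS2 2, where SMARCAD1 had an adjusted p of 0.0309, and 1 without broiler CON 1 and CON 2 together.

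Among the gene lists, cholesterol synthesis passed the test of the difference. Its members lay lower in FS2 roosters and not in FS2 chicks, with 18 of 20 differences below 0 (median log2 -0.32, camera adjusted p = 0.0235; adjusted p = 0.846 with an estimated correlation; 0 members when adjusted over the list alone). The adjusted p was 0.361 without rooster CON 3, 0.413 without rooster FS2 1, 0.0757 without rooster FS2 3, 0.168 without broiler CON 3, 0.137 without broiler FS2 2 and 0.0735 without broiler FS2 3. The number of lists past the test of the difference went from 1 to 8 without rooster FS2 1, 4 without rooster CON 2, 3 without each of rooster FS2 2, rooster FS2 3 and broiler CON 2, and 6 without broiler CON 1. It was 0 without rooster CON 3, broiler CON 3 or broiler FS2 2, and 6 without broiler CON 1 and CON 2 together. Across 9100 genes measured at both stages, the fold changes of fathers and chicks had a Pearson r of 0.238 and a Spearman rho of 0.173. Genes are not independent replicates, and 24 of 100 regroupings of the diets within each stage gave an absolute r as large (permutation p = 0.24, two-sided, where 0.01 is the smallest possible). The highest other value was 0.374.

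Far more genes passed by age than by diet. Adult rooster liver was higher in immune cell and interferon genes, and 1-day-old liver in cell cycle and respiratory chain genes, by list tests that passed with the preset correlation and not with an estimated one (adjusted p = 0.379, and adjusted p = 0.581 for the respiratory chain). PIGR, which carries immunoglobulins into bile, was at 829 ± 194 FPKM in roosters and 0.788 ± 0.373 in chicks (log2 8.86, limma adjusted p = 4.45e-11). Ii, the invariant chain of MHC class II (1039 ± 316 against 42.6 ± 9.69), the class II chain BLB1 (366 ± 154 against 19.9 ± 4.77) and the interferon-induced ISG12(2) (170 ± 135 against 4.90 ± 1.76) were higher in roosters. So were the stearoyl-CoA desaturase SCD (72.2 ± 57.8 against 0.434 ± 0.222, adjusted p = 2.13e-05), LYRM4, an iron-sulfur cluster assembly protein (62.4 ± 37.3 against 1.10 ± 0.169), the kinase SIK1 (107 ± 56.2 against 2.79 ± 0.552) and AGMO, an ether lipid monooxygenase (30.6 ± 18.6 against 0.160 ± 0.0838). HIST1H46 and FASN, fatty acid synthase, were called higher in roosters, but each was listed at 0 in 4 chick pools and at 151 and 2619.5, or 129 and 87.5, in the other 2. The FASN call was lost with values of 0 taken as missing (adjusted p = 0.457) and with CON libraries only (0.0577), and the HIST1H46 call with values of 0 taken as missing (0.214) and without broiler CON 1 and CON 2 together (0.111).

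Chick liver was higher in LFABP, a liver fatty acid-binding protein (5.46 ± 3.71 in roosters against 1781 ± 327, log2 -8.27, adjusted p = 1.93e-08), and in the lipases LIPC (0.630 ± 0.351 against 180 ± 39.3) and LPL (2.23 ± 1.29 against 58.0 ± 7.33). The creatine synthesis enzyme GATM (24.2 ± 13.4 against 641 ± 207), the fetal plasma protein AHSG (659 ± 290 against 7838 ± 1211), elastin (ELN, 3.18 ± 1.01 against 51.2 ± 10.5), OSGIN1 (4.85 ± 1.597 against 86.3 ± 19.2) and the progestin receptor PAQR7 (1.13 ± 0.324 against 31.0 ± 11.2) were also higher in chicks. Metazoa_SRP ran from 9.81 to 96.7 in chick pools and from 0 to 4.65 in roosters, and a second uc_338 row on chromosome Z (31228843 to 31399996) was listed at 0 in all 6 roosters and in broiler FS2 2 and at 19.6 to 25.2 in the other 5 pools. In total 4999 of 9869 genes passed, 2330 higher and 2669 lower in roosters. Age and pooling go together in this comparison, and the labels do not give the sex of the chicks.

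Of the 26 lists, macrophages, cell cycle, lymphocytes and heterophils had the largest median differences by stage. Interferon response, at a median of 1.26, lay below acute phase and inflammation at 1.65. In roosters 14 of 15 lymphocyte genes were higher (median log2 2.01, camera adjusted p = 2.6e-09; 15 when adjusted over the list alone), such as the T-cell receptor chains CD3D (42.1 ± 22.6 against 1.93 ± 0.444) and CD3E (13.6 ± 5.77 against 0.448 ± 0.152). So were 12 of 13 macrophage genes (adjusted p = 7.41e-09; 12 over the list alone), such as ITGB2 (28.0 ± 8.38 against 3.96 ± 0.792) and the protease CTSS (460 ± 167 against 63.9 ± 14.3). Of 16 interferon response genes 14 were higher (adjusted p = 3.18e-07; 16 over the list alone), such as IFI27L2 (416 ± 236 against 23.6 ± 4.93) and OAS*A (22.6 ± 14.2 against 1.77 ± 0.383), and 6 of 9 heterophil genes (adjusted p = 0.000952; 8 over the list alone), such as LYG2 (57.7 ± 41.2 against 8.50 ± 4.24). Cell cycle genes ran the other way, with 25 of 27 lower and 1 higher (median -2.15, adjusted p = 1.7e-13; 26 over the list alone), such as RRM2, a subunit of ribonucleotide reductase (1.95 ± 1.62 against 28.4 ± 9.19), and the mitotic kinase CDK1 (4.61 ± 3.24 against 44.3 ± 8.42). Each of these 5 lists had an adjusted p = 0.379 with an estimated correlation.

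Metabolic lists moved too. Oxidative phosphorylation was lower in roosters with 27 of 33 genes (median -1.08, adjusted p = 3.82e-08; 28 when adjusted over the list alone; adjusted p = 0.581 with an estimated correlation), such as NDUFV1 (70.7 ± 18.7 against 264 ± 55.9) and ATP5B (253 ± 36.0 against 939 ± 241). Folate and one-carbon metabolism was lower with 14 of 21 genes and 2 higher (adjusted p = 0.0121; 17 over the list alone; adjusted p = 0.379 with an estimated correlation). Its members included SLC19A1, the reduced folate carrier (13.4 ± 3.89 against 99.6 ± 25.5, log2 -2.82), and TYMS (1.84 ± 1.16 against 11.9 ± 2.41). The methionine cycle list was lower with 8 of 15 genes and 2 higher (adjusted p = 0.044; 10 over the list alone; adjusted p = 0.379 with an estimated correlation). Within it GAMT, of creatine synthesis, was at 95.2 ± 56.1 against 345 ± 132.9 (adjusted p = 0.0507 with CON libraries only), while the row of MAT1A, which makes S-adenosylmethionine, was higher in roosters (1977 ± 566 against 416 ± 73.5). Cholesterol synthesis was higher with 9 of 20 genes and 2 lower (adjusted p = 0.044; 11 over the list alone; adjusted p = 0.737 with an estimated correlation), such as INSIG1 (430 ± 193 against 44.8 ± 15.6) and HMGCS1 (2710 ± 543 against 432 ± 93.9). The cholesterol list was at 0.0989 without rooster CON 3, 0.0624 without rooster FS2 2, 0.0659 without broiler CON 1 and 0.0849 without broiler FS2 1. The methionine list was at 0.0610 without rooster CON 2, 0.0724 without rooster FS2 1 and 0.109 with CON libraries only.

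Acute phase and inflammation genes were higher in roosters with 8 of 12 and lower with 2 (adjusted p = 0.0121; 10 when adjusted over the list alone; adjusted p = 0.379 with an estimated correlation), such as the ceruloplasmin row (CP, 354 ± 103 against 17.0 ± 3.65). The haemoglobin-binding PIT54 row was listed at 0 in 5 roosters and at 7309 in CON 1, against 3912.5 to 6557 in chicks, and its call was lost with CON libraries only (0.0860). Endothelial genes were higher with 8 of 17 (adjusted p = 0.0211; 8 over the list alone; adjusted p = 0.643 with an estimated correlation), such as CDH5 (48.2 ± 8.92 against 22.4 ± 5.03) and LYVE1, a marker of liver sinusoids (15.3 ± 3.35 against 6.75 ± 1.38). Without rooster FS2 2 that list was at 0.0552. The list of epididymis and duct epithelium was lower with 4 of 8 (adjusted p = 0.0459; 5 over the list alone; adjusted p = 0.379 with an estimated correlation). Those that moved furthest were general epithelial genes, E-cadherin (CDH1, 43.0 ± 8.30 against 99.5 ± 14.1) and the keratin row KRT4,KRT8 (16.8 ± 3.03 against 40.0 ± 9.50). That call was lost without rooster CON 2 (0.0690), rooster FS2 2 (0.0552), rooster FS2 3 (0.0503), broiler CON 1 (0.0670) or broiler CON 1 and CON 2 together (0.0745), and without a minimum value (0.119).

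**Figure D3:**
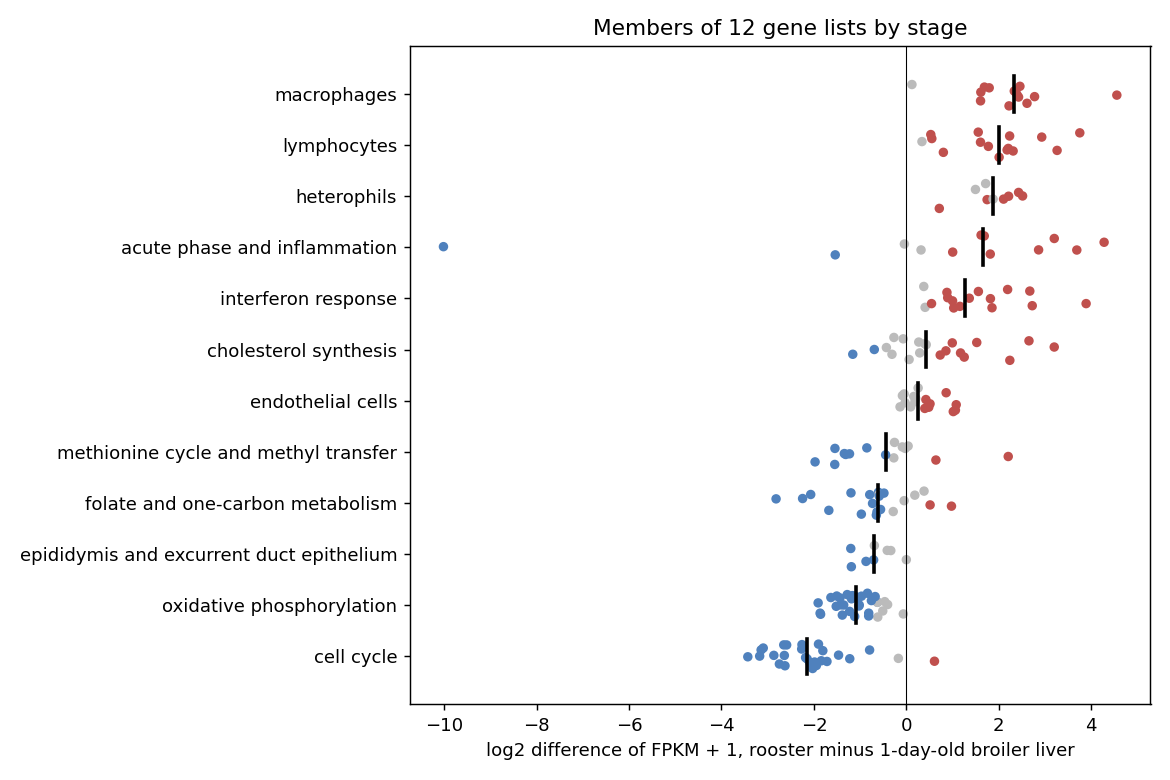
Log2 difference of FPKM + 1, rooster minus 1-day-old broiler liver, of the members of the 12 gene lists that passed by stage, with a point per gene. Red and blue points passed the adjusted test as higher or lower in roosters, grey ones did not, and the black line is the list median (2.01 for lymphocytes, -2.15 for cell cycle).

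Among liver lncRNAs 1 transcript of chick liver passed the test by diet of the father. TCONS_00024912 (chromosome 2, 7826136 to 7834289), which shares a splice junction with INSIG1 at the same locus per the file's class code, was at 10.6 ± 5.20 FPKM in FS2 and 0.0723 ± 0.0952 in CON (log2 3.31, SE 0.38, limma adjusted p = 0.0358). In roosters it ran from 0.00919 to 47.9 in CON and from 0.0180 to 25.5 in FS2. The call was lost without CON 2 (0.0506), CON 3 (0.204), FS2 2 (0.0770), FS2 3 (0.0673) or CON 1 and CON 2 together (0.468), without a minimum (0.320), with a mean of at least 5 (0.741) and with median centring (0.176). Of 3211 broiler lncRNAs 163 had an unadjusted p under 0.05 (161 by chance), and of 3491 in roosters limma called 0, with 73 at that p (175 by chance). The rooster count was 1 without FS2 1. The broiler count was 9 (8 lower) without CON 1, 2 lower without CON 3, 4 (3 higher) without FS2 1, 0 without FS2 2 or FS2 3, and 8 lower without CON 1 and CON 2 together. The median log2 difference over the tested lncRNAs was 0.12 in favour of FS2 at both stages. Summed FPKM over all lncRNA rows went the other way in roosters, at 20384 to 64966 in FS2 against 67130 to 92413 in CON. In chicks the sums were 27032 to 39725 in FS2 against 30810 to 147930 in CON. A general rise of lncRNAs in FS2 is therefore not shown.

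Liver miRNAs did not pass by diet at either stage. Each value is that of 1 sequence, and a suffix such as _R-2 is the table's name for a variant of the reference miRNA. In roosters gga-miR-148a-5p was at 103 ± 21.8 (authors' normalized value) in FS2 and 56.0 ± 9.29 in CON, gga-miR-223_R-2, of a myeloid miRNA, at 78.0 ± 16.7 against 46.0 ± 9.09, and gga-miR-33-5p, which lies within a sterol regulatory gene, at 2093 ± 266 against 1475 ± 92.8. Also at higher values were gga-miR-1731-5p (20.6 ± 9.18 against 9.04 ± 3.27) and gga-miR-101-3p_R-1 (84271 ± 9338 against 62539.5 ± 12552). On the lower side were tgu-miR-1784-3p_1ss11GA (33.9 ± 17.6 against 84.3 ± 15.4), gga-miR-1784-5p (31.9 ± 20.6 against 81.4 ± 25.5), gga-miR-3525 (34.7 ± 4.05 against 61.7 ± 15.3), gga-miR-9-5p (184 ± 30.3 against 278 ± 17.9) and sha-miR-125a_R+2 (1949 ± 38.6 against 2640.03 ± 368). In chicks the variant gga-miR-101-3p_L-1R+2 was at 43.5 ± 2.26 against 25.9 ± 10.0, gga-miR-205b at 34.0 ± 4.55 against 21.4 ± 6.10 and gga-miR-454-3p at 27183 ± 4877 against 22380.1 ± 1019.9. Wider spreads were those of mmu-miR-6238_L-1R-3_1ss12TC (42.8 ± 42.9 against 11.8 ± 7.82) and age-miR-93_L+1 (37.2 ± 29.5 against 15.6 ± 6.04). At lower values were gga-miR-1434_R+3 (28.6 ± 8.51 against 77.2 ± 27.7), gga-miR-1618-3p_L+1 (6.37 ± 1.32 against 14.6 ± 1.82) and gga-miR-3528_R+1 (11.0 ± 4.49 against 30.1 ± 12.8). The muscle miRNA variants gga-miR-1b-3p_R+1 (16.9 ± 8.62 against 211 ± 199) and gga-miR-133c-3p_1ss22CT (105 ± 29.2 against 993 ± 1372) were also among the lower ones. The latter was at 2575 in CON 2, the pool with the heart transcripts, and gga-miR-1b-3p_R+1 at 404 in it, 224 in CON 1 and 6.40 in CON 3. In roosters edgeR called 0 of 370 (11 at an unadjusted p under 0.05, 18 by chance) and DESeq2 0, and in chicks edgeR called 0 of 359 (15 at that p, 18 by chance) and DESeq2 0. Without CON 3, 1 miRNA passed in chicks, gga-miR-1b-3p_R+1 (adjusted p = 0.0306). Without a filter on low counts edgeR called 41 in chicks, among them gga-miR-133c-3p_1ss22CT (adjusted p = 6.93e-22), gga-miR-1b-3p_R+1 (2.16e-16), gga-miR-1434_R+3 (0.0213) and mmu-miR-6238_L-1R-3_1ss12TC (0.0422), and 2 in roosters.

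By stage the miRNAs parted clearly. The variant gga-miR-155_R+1, of an activator of immune cells, was at 294 ± 85.8 in roosters and 28.4 ± 12.5 in chicks (log2 3.58, edgeR adjusted p = 1.65e-06), with oan-miR-1388-3p_R+2 (35.7 ± 16.0 against 0.424 ± 0.829), tgu-miR-1784-3p_1ss11GA (59.1 ± 31.3 against 1.62 ± 1.57), gga-miR-1784-5p (56.7 ± 34.1 against 2.13 ± 1.59) and gga-miR-29b-2-5p_L-2 (30.4 ± 11.3 against 2.74 ± 1.82) also higher. The epithelial gga-miR-205a_R+1 was at 8.34 ± 1.86 against 459 ± 210 (log2 -5.56, adjusted p = 3.82e-07), and gga-miR-205b and gga-miR-6606-5p were at 0 counts in all 6 roosters and at 27.7 ± 8.40 and 10.2 ± 8.67 in chicks. Also lower in roosters were oha-miR-7-1-3p_1ss10GA (0.214 ± 0.524 against 49.3 ± 28.2) and PC-3p-68190_58 (0.274 ± 0.672 against 11.9 ± 3.35). Of 409 miRNAs edgeR called 259, 129 higher and 130 lower in roosters, and DESeq2 251.

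In sperm, where each level is 1 pool, a few genes lay at least 2-fold from CON in the same direction at all 4 folate levels. ITIH2, a hyaluronan-binding plasma protein, was at 0.378 FPKM in CON and at 3.88, 2.61, 3.80 and 3.86 in FS1 to FS4. USP12, a deubiquitinase, went from 0.420 to 3.53, 1.84, 4.07 and 3.61, and the olfactory receptor OR6A2 from 0.507 to 2.16, 3.35, 2.52 and 3.52. PURG was listed at 0 in CON and at 1.27, 1.73, 2.82 and 5.85 at the other levels. RNaseP_nuc, the nuclear RNase P RNA, went from 0.3045 to 1.86, 3.08, 3.39 and 6.44. Rows named uc_338 went both ways: XLOC_087109 was at 1.07 in CON and 14.9, 5.98, 7.72 and 27.1 at the other levels, while XLOC_077674 went from 28.6 to 1.69, 0.937, 2.88 and 1.92, XLOC_032853 from 29.9 to 1.28, 1.15, 1.22 and 11.6, and XLOC_069253, XLOC_007619 and XLOC_215025 from 12.4, 10.9 and 6.69 to between 0.876 and 1.80. On the lower side SNORA21, a small nucleolar RNA, was at 310 in CON and listed at 0 at the other 4 levels. The spliceosomal RNA U1 went from 19.5 to 3.86, 1.27, 1.18 and 1.75 on one row (XLOC_003814) and from 13.3 to 2.24, 0.953, 1.68 and 2.06 on another (XLOC_163925), the kinase CDKL2 from 10.2 to 1.54, 3.51, 0 and 3.51, and the calmodulin regulator PCP4 from 9.31 to 3.55, 1.09, 0.929 and 1.43. Under median centring USP12, OR6A2, PURG and RNaseP_nuc fell short of 2-fold at 1 level or more (mean log2 ratios 1.30, 1.09, 1.58 and 1.503).

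Across 14750 sperm mRNA rows, 31 met this rule, 16 higher and 15 lower. Single levels gave 181 higher and 68 lower (FS1), 281 and 94 (FS2), 94 and 70 (FS3) and 630 and 54 (FS4). The median row lay 0.22, 0.27, 0.16 and 0.45 above CON on the log2 scale. With each library centred on its median the splits were 117 and 98, 112 and 147, 77 and 88, and 150 and 134, with 7 higher and 22 lower at all 4 levels. All 4 ratios share the CON pool. Unchanged libraries, CON among them, were simulated around each row's mean with the spread seen between the 4 folate levels. They gave a mean of 12.6 higher and 20.1 lower at all 4 levels. These simulations, used for lncRNAs and miRNAs as well, hold no shift of a whole library. The centred 7 and 22 are therefore the counts to set beside them for mRNAs. The mean correlation of ratios between levels was 0.469 (simulated 0.499) and their mean covariance 0.0748 (simulated 0.0704). Independent lists would give 0.000939 higher and 7.53e-06 lower at all 4 levels. The simulated counts reached 22 higher and 37 lower, above both the real and the centred counts. With a single CON pool the controls cannot be split, so part of any excess over independent lists may come from that pool.

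Of 119914 sperm lncRNAs, 353 met the rule, 67 higher and 286 lower, against simulated means of 117 and 251. Independent lists would give 0.0109 and 0.00753. Their mean correlation was 0.465 (simulated 0.5001) and their covariance 0.0840 (simulated 0.0894). Single levels gave 2540 higher and 1395 lower (FS1), 1747 and 2520 (FS2), 2482 and 1554 (FS3) and 1712 and 2378 (FS4), which under centring were 1716 and 2053, 1708 and 2564, 2054 and 1881, and 1303 and 3083. Of 409 sperm miRNAs 3 were higher at all 4 levels and 0 lower (simulated 7.91 and 8.17; 0.0528 and 0.00876 from independent lists), with a mean correlation of 0.175 (simulated 0.493) and a covariance of 0.111 (simulated 0.542). They were PC-3p-98308_28 (0.991 in CON and 10.7, 24.8, 19.2 and 8.61 in FS1 to FS4), gga-mir-1648-p5_1ss11TG (1.98 and 8.20, 11.2, 53.0 and 6.03) and PC-5p-100222_27 (4.96 and 17.2, 29.8, 23.7 and 17.2). All of them fell short with a pseudocount of 10. Single levels gave 36 higher and 24 lower (FS1, 45 and 19 under centring), 40 and 26 (FS2), 66 and 32 (FS3) and 38 and 30 (FS4). Of the gene lists, 6 of 104 medians (26 lists at 4 levels) lay in the top 2.5% of random lists and 0 in the bottom 2.5%. Chance would give 5.2 over both ends together if the medians were independent, which levels sharing a CON pool are not. At all 4 levels 0 lists lay at the same end.

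Levels in the sperm libraries hardly differed between genes of unrelated tissues. List medians in sperm ran from 0.819 FPKM (testis and sperm genes) to 1.82 (circadian clock), against 0.088 to 1736 in liver. The interquartile range over genes of log2(FPKM + 1) was 0.51 to 0.58 in the sperm libraries and 3.12 to 3.44 in liver. This scale narrows the spread of low values such as those of sperm.

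**Figure D4:**
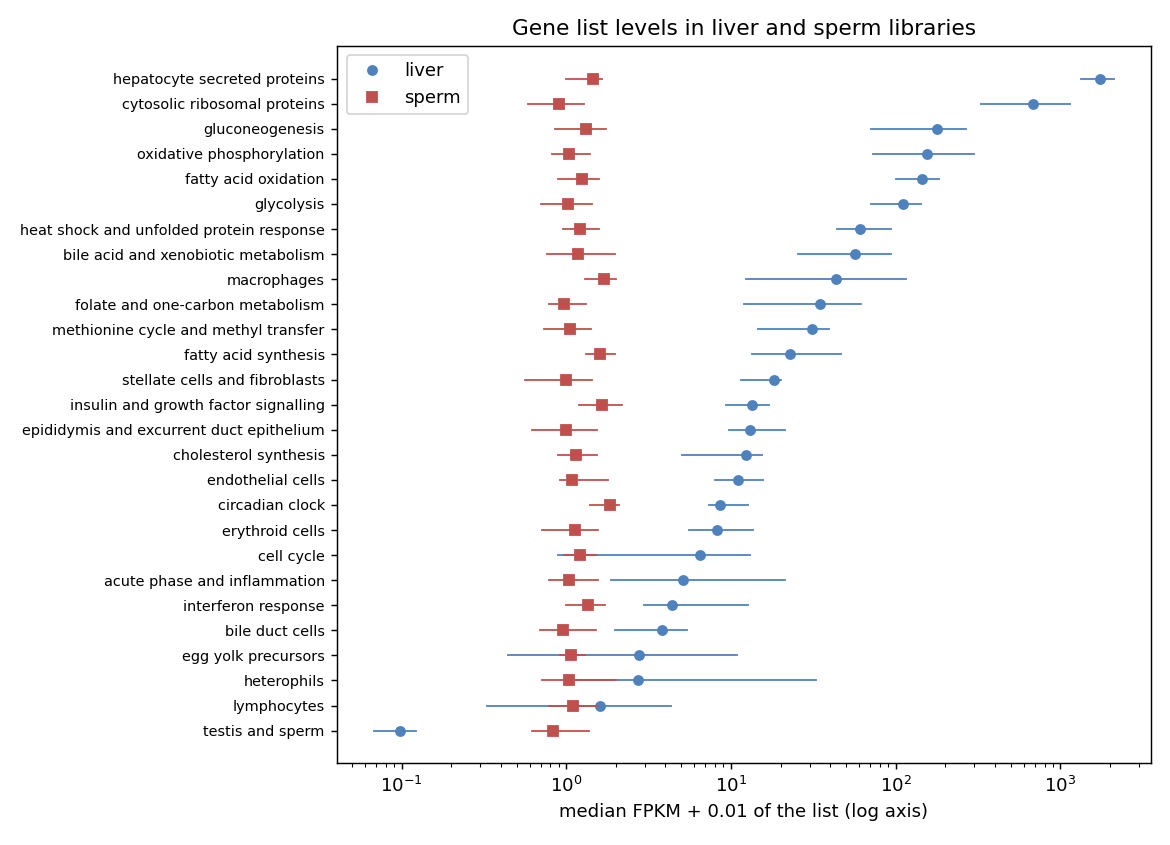
Median FPKM + 0.01 (log axis) of 27 gene lists in liver (circles) and sperm (squares). Each point is the median over libraries and each line the range over libraries, and sperm medians stay between 0.819 and 1.82 FPKM while liver medians span 0.088 to 1736.

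The authors' deposited tables list more genes than passed here, at unadjusted p-values. The authors' deposited table for rooster liver lists 42 mRNA genes (26 higher and 16 lower in FS2) and that for chick liver 82 (13 and 69). Of those on a tested row, 36 of 36 rooster genes and 59 of 61 chick genes lay in the same direction here. Of these tested genes, 12 in roosters and 15 in chicks had an unadjusted limma p under 0.05. The listed genes were picked for a difference between the same libraries, so the shared direction is largely built in and is no independent support. The authors' deposited tables for both stages share 6 genes, 4 of them in the same direction. MYCL, a MYC family transcription factor, is listed by the authors' deposited tables at 15.6 FPKM in FS2 against 6.85 in rooster liver and at 8.16 against 3.89 in chicks. ANGPTL4, an inhibitor of lipoprotein lipase, is listed there at 6.19 against 2.08 and 5.21 against 2.60, the gluconeogenic enzyme PEPCK at 481 against 30.03 and 14.0 against 6.86, and U3 at 7496 against 22524 and 2472 against 9259. THRSP (41.6 against 1.53 in roosters, 5.22 against 116 in chicks) and NT5C3B (4.09 against 11.4, 19.4 against 8.92) go opposite ways in the authors' deposited tables. Among 8733 genes tested at both stages, 27 are in the rooster and 43 in the chick table. In both are 5, of which 3 go in the same direction. If every gene were equally likely to be listed, 0.133 would be in both, an assumption that was not tested. In the limma fits, rooster then chick, MYCL had log2 differences of 0.90 and 0.79 (unadjusted p = 0.0169 and 0.00508), ANGPTL4 of 1.12 and 0.59 (0.0395 and 0.0506) and PEPCK of 1.40 and 0.86 (0.424 and 0.281). NT5C3B had -0.014 and 0.093 there (unadjusted p = 0.969 and 0.668) and THRSP 3.40 and -3.12 (0.00558 and 0.118).

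The authors' deposited chick table holds 7 genes of the heart muscle list, all lower in FS2, among them NPPB at 0.297 against 225 FPKM, MYL3 at 0.328 against 45.6 and Myl2 at 0.147 against 14.3. It also holds 2 of the stomach list, CHIA at 4.94 against 45.4 and CTSE at 0 against 5.12. Of 73 genes of that authors' deposited table on a single row, 13 (17.8%) were at least 2 times every other pool in CON 2 and 15 (20.5%) in CON 1, against 36 (0.397%) and 43 (0.475%) of 9059 genes. The shares were 2.74% against 0.0993% in CON 3, 1.37% against 0.0552% in FS2 1 and 1.37% against 0.0442% in FS2 2. FS2 3 had 0% against 0.0442%. The 9059 genes had a mean of at least 1 FPKM over the broiler pools, a minimum not applied to the 73, so the shares are not fully alike. The 73 are listed for a difference between the same pools, so a share above that of all genes is partly built in. For lncRNAs the authors' deposited tables list 64 in rooster liver (53 higher), 21 in chick liver (16 higher) and 462, 633, 527 and 557 in sperm from FS1 to FS4. For sperm mRNA genes the authors' deposited tables list 111 (104 higher), 261 (250), 68 (60) and 208 (200). For miRNAs the authors' deposited tables list 31 in rooster liver (18 higher), 22 in chick liver (10) and 81, 115, 208 and 92 in sperm.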

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

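The test of lists for the difference between rooster and chick liver, the test of all rows and the count of other splits were chosen after results had been seen. Cholesterol synthesis genes drew attention because their folate effect differed between fathers and chicks: 18 of 20 differences lay below 0 (camera adjusted p = 0.0235), and 0 members passed on their own. Over its alternatives the adjusted p ran from 1.89e-07 (without rooster FS2 2) to 0.846 (estimated correlation). Regrouping the libraries gave at least 1 list in 99 of 100 splits, with 1 in the real split and 13 in the highest other, so chance is not excluded. With an estimated correlation the real split gave 0 lists, and no test separated a structure of the libraries from correlation between the genes of a list. For single genes all 100 splits gave as many as the real 0, with 4 in the highest other.

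Rows without a gene symbol or Ensembl identifier, which the gene comparisons do not use, held a signal above the CON pools in FS2 chick liver. With all rows tested, limma called 4, which are uc_338 and 3 unnamed rows on chromosome 1. XLOC_001520 (100434669 to 100434838) was listed at 0 in all 3 CON pools and at 195, 131 and 116 FPKM in the FS2 pools (log2 7.18, adjusted p = 6.02e-06). XLOC_004436 (159308717 to 159308888) was at 77.6, 52.2 and 50.1 in FS2 (log2 5.90, adjusted p = 7.92e-06) and XLOC_002172 (166615699 to 166615893) at 10.2, 13.3 and 13.4 (log2 3.72, adjusted p = 4.85e-05), both also listed at 0 in every CON pool. In roosters these rows did not follow the diet in the same way: XLOC_001520 was at 463, 0 and 0 in CON and at 211, 0 and 185 in FS2, XLOC_002172 at 29.4, 0 and 81.6 in CON and at 10.4, 311 and 0 in FS2, and XLOC_004436 at 423, 0 and 189 in CON and at 0 in all 3 FS2 birds. A value of 0 in these tables can be a failed estimate, and of 79 rows named uc_338 in liver 20 were at 0 in at least 1 library and at 10 or more in another.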

How the results depend on the processing

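Added after the data had been seen were the tests with all rows, with values of 0 as missing, without small-RNA rows, with CON libraries only and without broiler CON pools 1 and 2 together, and the list tests by stage and of the difference with all their alternatives. The stage comparisons kept most of their calls: 4424 to 5044 genes, 244 to 280 miRNAs and 10 to 13 lists leaving out 1 library each, against 4999, 259 and 12. They gave 3332 genes with a mean of at least 5 FPKM, where fewer genes are tested, and 2892 genes and 154 miRNAs with CON libraries only, where fewer samples are tested. Of 187 named results, 2932 of 3030 values under alternatives kept direction and side of the threshold, 78 were weaker (38 of them leaving out 1 library), 6 stronger, 7 no longer met the size rule and 7 turned sign. Most genes and miRNAs named by diet were far from the threshold, and those named by stage were mostly the largest changes. That share was therefore largely set by the naming rule and is no measure of how firm the results are. For the changes that follow the cause was not tested.

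The diet comparisons were thin. Leaving out 1 library each gave 0 to 2 genes in rooster liver, 1 to 3 in broiler liver and 0 to 3 for their difference, 0 to 1 and 0 to 9 lncRNAs, 0 to 0 and 0 to 1 miRNAs, and a shared fold correlation of 0.00295 to 0.292. In broiler liver the count of 1 gene went to 0 with all 12 libraries in the fit, 0 without small-RNA rows, 3 with 0 as missing, 4 with all rows and 7 without CON 1 and CON 2 together. The 3 with 0 as missing were PGA, ATP4B and ENSGALG00000016165, each carried by broiler CON 1. Without CON 1 and CON 2 the difference of the folate effect gave 1 gene and broiler lncRNAs 8. In that setting PEMT (-0.025), acl (-0.0079), SREBP-1 (-0.085), ACSL1 (-0.045) and gga-miR-1b-3p_R+1 (1.497) turned sign on the log2 scale, none of them past the threshold in either setting. The broiler lncRNA count was 0 without a minimum, 0 with a mean of at least 5 and 0 with median centring. Without a filter on low counts miRNAs gave 2 in roosters and 41 (33 lower) in chicks, 4 of them named miRNAs that did not pass with the filter.

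Gene lists rested most on the assumed correlation: with an estimated correlation the counts were 0 in rooster liver, 0 in broiler liver, 0 by stage and 0 for the difference. Leaving out 1 library gave 2 to 8 lists in rooster liver, 3 to 11 in broiler liver and 0 to 8 for the difference, and 6 for the difference without broiler CON 1 and CON 2. Ribosomal proteins turned to higher in FS2 without rooster FS2 1 (adjusted p = 0.0142) and without broiler CON 3 (0.950), with ranges of 5.05e-05 to 0.762 and 6.44e-13 to 0.950 leaving out 1 library each. With the replicate number as a block, rooster lists went to 6, and it moved no other count of calls by over 1.5 times. The numbers do not pair the libraries: correlations of same-numbered deviations were 0.392, 0.171 and 0.0968 in roosters and 0.0124, -0.0150 and 0.305 in broilers, and not every library correlated best with its own number.

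Sperm counts moved with the pseudocount and the minimum. With 0.1 FPKM in place of 1, mRNA rows at 2-fold were 171 at all 4 levels and 853, 2338, 620 and 4019 from FS1 to FS4, and lncRNAs 2365 and 17442, 19834, 16654 and 23082. A 5 times higher minimum left 11 mRNA rows at all 4 levels (89, 104, 53 and 134 at single levels), 116 lncRNAs (594, 702, 543 and 735) and 0 miRNAs (13, 21, 27 and 15), where fewer rows are counted. Centring left 284 mRNA rows in FS4, and 19 met the rule at all 4 levels without small-RNA rows. For miRNAs a pseudocount of 10 gave 0 at all 4 levels and 20, 40, 57 and 24 at single levels, and no minimum gave 33 and 341, 454, 639 and 308. Not run were a pseudocount for liver miRNAs, meant for normalized values only, and a test per transcript, since the table rows are genes. Read depth limits the miRNA values, with the fewest liver counts in broiler FS2 3, and is unknown for the FPKM.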

Other observations

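The gene and miRNA counts by stage and the counts by diet come from planned tests. Every other test below except the one on whether libraries differ together in ribosomal protein genes was chosen after the result had been seen. By stage, where 4999 of all 9869 genes passed, single genes of fuel metabolism passed in both directions and its lists did not pass camera. In glycolysis 4 genes were higher and 7 lower in roosters of 16 (adjusted p = 0.329; 13 when adjusted over the list alone). The 2 lactate dehydrogenase subunits went opposite ways, LDHA at 395 ± 152 FPKM in roosters against 103 ± 27.2 in chicks and LDHB at 417 ± 158 against 1380 ± 277. In fatty acid synthesis 8 genes were higher and 5 lower of 16 (adjusted p = 0.149; 14 over the list alone), led by the desaturase SCD. In fatty acid oxidation 3 were higher and 9 lower of 20 (adjusted p = 0.191; 12 over the list alone): PDK4, which holds back pyruvate oxidation, was at 197 ± 131 against 33.3 ± 4.78, and ETFA, which passes electrons from acyl-CoA dehydrogenases to the respiratory chain, at 136 ± 26.1 against 311 ± 35.7. Plasma proteins secreted by hepatocytes were mixed, with 7 higher and 3 lower of 19 (adjusted p = 0.668; 10 over the list alone), a median of -0.19 and a test direction of higher.

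Transcripts of other organs in 2 of 3 broiler CON pools may come from tissue taken along with the liver. In CON 2 the heart list stood at 167.4 times the other pools, while fast skeletal muscle genes reached 0.00826 of the heart median, which argues against that muscle. Smooth muscle genes were at 1.82 times the other pools (13.95 against 7.66 FPKM), a baseline at which some added smooth muscle stays open. In CON 1, 63.16% of the stomach genes were at 1 FPKM or more and over 5 times the other pools (GKN2 908.5, CTSE 34.4, with CHIA and GIF also expressed by adult liver), against 0% of the intestinal genes, which argues against intestine. Against a response to the diet of the father shared by CON pools, each list stayed within 1.28 times the highest FS2 pool in the CON pools other than its own, and a difference particular to the birds of 1 pool stays open.

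The even levels of sperm long RNA, whatever the tissue a gene belongs to, are consistent with a background such as genomic DNA: the testis and sperm list never exceeded 0.8381 of the hepatocyte list in any of 5 libraries. Blood or epididymal cells would raise their own lists, and the highest ratio of any such list to hepatocyte genes was 1.388. For scaling by the authors, the widest interquartile range of log2(FPKM + 1) in sperm was 0.1872 of the narrowest in liver. On that scale a factor per library also changes the spread of low values, so this range cannot decide. Ratios between lists are left unchanged by such a factor, and stayed between 0.5377 and 1.395 of the hepatocyte list in the sperm libraries. Liver list medians ran from 0.088 to 1736 FPKM, so these values argue against a factor per library alone. Unannotated rows had medians near those of annotated rows (0.939 and 0.762 FPKM in CON, 1.15 and 1.36 in FS4). Beyond blood and epididymal cells no biological explanation was tested, and low RNA amounts stay open.

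Ribosomal protein genes lower in FS2 liver at both stages may reflect libraries that differ together in these genes. At each stage 7 of the 9 other splits of the 6 libraries also put the list past the test, with adjusted p down to 1.58e-10 in roosters and 7.72e-20 in chicks. Leaving out 1 library turned the direction at each stage, and library medians ran from 328 to 801 FPKM in roosters and 539 to 1142 in chicks. At least 5 of the 9 other splits gave a smaller adjusted p than the real one, so an effect of folate level cannot be told apart from differences between libraries with 3 per group.

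Other groupings of the libraries set the size of chance. By stage, 1 of 100 splits, the real one, gave as many genes (4999, highest other 1406) and 1 of 100 as many miRNAs (259, highest other 100), so chance is excluded there. For lists by stage 7 of 100 gave as many (12, highest other 13), and chance is not excluded. With 3 against 3 there are 10 splits, too few for a share under 0.05. There, 10 of 10 gave as many genes in rooster liver (real 0, highest other 1), 10 as many lncRNAs (0 and 5), 10 as many miRNAs (0 and 1) and 10 as many lists (3 and 9). In broiler liver the numbers were 4 of 10 for genes (1 and 2), 4 for lncRNAs (1 and 2), 10 for miRNAs (0 and 0) and 7 for lists (6 and 10). Splits with several times the real number of lists point to a structure of the rooster libraries other than diet or to correlation between list genes above the preset one, which no test separated.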
